A study of Mus musculus with 58 samples.

How the data were processed

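RNA sequencing of cultured mouse B16-F0 melanoma lines came as 2 tables, and single-cell RNA sequencing of mouse lymph nodes came as 3 count matrices. Per the labels, all lines were grown in DMEM with 10% serum and RNA was extracted with the RNeasy Plus mini kit. The libraries of the generation table were built by Centrillion with the TruSeq RNA kit, and those of the guide table by MedGenome with the TruSeq stranded mRNA kit, per the labels. Per the labels, reads were trimmed with Trimmomatic 0.36, checked with FastQC 0.11.3 and quantified with Salmon 0.7.2 against GRCm38. Both tables as deposited by the authors hold TPM per gene. Per the labels, the authors also used DESeq2, and no output of it was used here. The single-cell matrices hold UMI counts per the file headers, and no upstream step was stated for them beyond the software name in the header. The 58 samples of the series include 12 ATAC samples, which were not analysed here, and exome data were not analysed here either. No genome sequence was used here, and no reads were remapped.

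The generation table held 32 libraries and 48523 genes after 27 names that had been turned into dates were left out; these held at most 0.181% of the TPM of a library. The guide table held 54281 Ensembl identifiers, of which 54107 matched a gene symbol, and identifiers without one held at most 0.0046% of TPM. 205 identifiers shared a symbol and were kept apart. Guide or vector numbers in most column names of this table differ by 1 from those in the sample titles. Columns were therefore joined to samples by line and targeted gene. The sgIfnar1 number of the library with both receptor guides is the same in both, and the NBF0IFNRKOLN1 names match. Newer symbols of 4 genes were written under the older symbols Mb21d1, Cyr61, Ctgf and Figf. Read depth is not known for either table, and no counts were inferred.

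Tests used log2(TPM + 1) in limma 3.58.1 (R 4.3.3, with data.table in version 1.17.8), with a moderated two-sided test, a mean-variance trend and Benjamini-Hochberg adjustment over all genes tested at 0.05. A gene was tested if it reached 1 TPM in at least 3 generation libraries or 2 guide libraries, which gave 14194 genes (14103 for the slope) and 12795 genes. Because of the added 1, log2 differences understate the change of genes with low TPM. Before the data were examined, generations 1 to 3 were set as early (n = 10), 4 and 5 as intermediate (n = 6) and 6 to 9 as late (n = 13), since the labels give no boundary, and the tests, gene lists, alternatives and the rule for naming genes were fixed. The 4 stages, parental (n = 3) included, entered 1 fit. A further fit took generation as a number over the 29 lymph node lines. For the guide table, 8 libraries entered a fit with line and guide as additive terms, so the 4 guide pairs were the replicates of the line difference and the 2 lines the replicates of each guide effect. The double-guide library and both libraries of NBF0IFNRKOLN1 were compared without a test, by the median log2 difference of a list and its percentile among 10000 random lists drawn in 20 bins of mean expression from 13097 genes. Nothing beyond the labels says that the parental cultures or the lymph node lines are independent, and the p-values measure the spread between these samples only.

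Gene lists covered interferon-stimulated genes, interferon-gamma and GTPase genes, interferon signalling components, MHC class I and class II presentation, checkpoint ligands, NK cell ligands, melanocyte differentiation, neural crest and dedifferentiation, mesenchymal and matrix genes, proliferation, hypoxia and glycolysis, fatty acid and sterol metabolism, nuclear oxidative phosphorylation, YAP targets, chemokines with lymphangiogenic factors, stress and immediate early genes, mitochondrial transcripts, and markers of lymphocytes, myeloid cells, fibroblasts and of endothelial and epithelial cells. For lymph node cells there were also lists of Treg genes, T cell checkpoint and exhaustion genes, naive T cell genes, T and NK effector genes, B cell activation genes and dendritic cell maturation genes. Some genes are in more than 1 list. Each list was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. A list score was the mean log2(TPM + 1) over the tested members minus the parental mean. Genes to be named were the 8 largest differences each way (4 for early against parental and the slope, 6 for each guide) among genes that passed with a mean of at least 5 TPM, without predicted gene models and ribosomal protein genes, up to 4 members per list with the smallest p, and 9 fixed genes.

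Single cells were processed with scanpy 1.11.5 and anndata 0.12.19 (Python 3.11.15, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0), and figures were drawn with matplotlib 3.10.9. Barcodes with at least 500 UMIs, at least 300 genes and under 10% mitochondrial UMIs were kept, and Scrublet doublets (expected rate 0.08) were removed per library. Counts were scaled to 10000 per cell; 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (2 iterations, seed 0) followed. A cluster was named for the class whose markers had the highest mean log2 ratio to the other cells. At least 3 markers of that class had to be at least 1.5-fold above the other cells and in at least 10% of cells. A cluster was left unnamed where other markers or cell cycle genes led its 10 top genes or its median UMI count was low. Each condition had 1 library, so no test was made between conditions. Class shares have exact Clopper-Pearson 95% intervals and ratios of CPM (UMIs of a gene scaled by the UMIs of the class) exact Poisson-based 95% intervals, which cover counting error only. Where a count was 0, the limit given is 3 counts of the total. Genes of a class with at least 200 cells were named by the 4 largest ratios each way among those of at least 2-fold with at least 100 UMIs. Shares of cells with a UMI of a gate gene were taken after thinning each cell to 2000 UMIs.

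Alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, other stage boundaries, only the groups compared, array weights, each library or guide pair left out, no guide term, an estimated correlation, no doublet removal, a mitochondrial limit of 5%, clustering resolutions of 0.5 and 2, and CPM without ribosomal and mitochondrial genes. The fits were tested on simulated data with known changes in 200 genes. Of 2-fold changes, the share recovered was 62.0% for late against parental, 72.5% for late against early, 59.5% for early against parental, 83.0% for the line difference, and 68.5%, 75.0% and 76.0% for sgStat1, sgIfnar1 and sgIfngr1. At 1.5-fold, 24.5% were recovered for late against parental, 18.5% for sgIfngr1 and 0 of 200 genes for sgStat1 and sgIfnar1. The simulated guide changes had the same size in both lines. The shares therefore do not hold for guide effects that differ between the lines. With sgStat1 the interferon-stimulated median was -0.29 in B16-F0 and -2.12 in LN6-987AL.

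Several choices followed a look at the data: a division of the generation libraries into 2 sets of 16 by the TPM of the predicted gene Gm24270 at 5720 TPM, with the set as a covariate or each set alone; the rules for naming clusters, including 5 cell cycle genes added by hand after 1 cluster had been given a wrong name; the final pattern for leaving out receptor gene segments; limits of 10 and 50 melanocyte UMIs; removal of barcodes shared between libraries; the thinning depth; leaving out guide libraries; the older symbols; interferon-stimulated genes within single clusters; and a minimum of 100 CPM for lymphocyte markers.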

Results

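RNA was measured by sequencing in 32 cultures of mouse melanoma cells. 3 libraries came from parental B16-F0, a pigmented mouse melanoma line, at different passages. The other 29 came from lines recovered from lymph node (LN) metastases after serial passage through lymph nodes, with 4 lines of generation 1, 3 each of generations 2, 3, 4 and 5, 5 of generation 6, 3 each of generations 7 and 8, and 2 of generation 9. Early lines (generations 1 to 3) numbered 10, intermediate lines (4 and 5) 6 and late lines (6 to 9) 13. A further 11 libraries came from lines carrying CRISPR guides against interferon receptor genes or Stat1, or the control guide sgLacZ, and from NBF0IFNRKOLN1. The labels of the 2 NBF0IFNRKOLN1 libraries name no guide. LN cells of 3 kinds of mice were profiled by single-cell RNA sequencing, with 1 library each from tumour-naive mice, mice bearing B16-F0 and mice bearing the generation 6 line LN6-987AL. The single-cell libraries held 9945, 11334 and 10092 barcodes, 63737770, 63742832 and 63799764 UMIs, and medians of 5586, 4643 and 4629 UMIs per barcode. The depth of the other libraries is not known, and their genes at 1 TPM or more numbered from 12009 to 12892 in the generation table.

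The comparison of late lines (n = 13) with the parental line (n = 3) asks what differs in melanoma cells after many passages through lymph nodes. Interferon-stimulated genes were higher: 37 of the 45 tested rose, 0 fell, and 42 rose when adjusted over the list alone. Their median log2 difference was 1.86. The mean list score was 1.83 ± 0.34 (SD, n = 13) in late lines, where the lowest was 1.17, against 0 ± 0.26 (SD, n = 3) in parental cells. Usp18 rose from 2.49 ± 0.975 TPM (SD) to 52.9 ± 23.6 TPM, a log2 difference of 3.81 ± 0.53 (SE, adjusted p = 1.2e-05). Dhx58 rose by 3.45 ± 0.42 (SE, adjusted p = 1.4e-06), Oas1a by 2.89 ± 0.30 (SE, adjusted p = 1.1e-07) and Stat1 by 1.86 ± 0.26 (SE, adjusted p = 1.1e-05), the last from 25.7 ± 5.99 to 96.8 ± 22.4 TPM (SD). Of 17 interferon-gamma and GTPase genes 12 rose and 0 fell (13 rose when adjusted over the list alone), with a median of 1.46; Igtp rose by 3.08 ± 0.29 (SE) to 18.9 ± 4.54 TPM. Interferon signalling components rose in 10 of 21 genes (adjusted over the list alone, 11 rose and 1 fell), among them the RNA sensors Ddx58 (2.36 ± 0.33, SE) and Ifih1 (1.86 ± 0.31, SE). Receptor genes did not pass, with Ifnar1 at 0.11 (adjusted p = 0.67) and Ifngr1 at -0.00 (adjusted p = 0.99).

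RNA of MHC class I presentation genes was higher in the late lines, with 15 of 22 genes rising, 0 falling and a median log2 difference of 1.11. Adjusted over the list alone, 16 rose. H2-K1, a classical class I gene, rose from 31.1 ± 9.96 to 193 ± 70.9 TPM (SD) and H2-D1 from 83.2 ± 19.9 to 306 ± 77.7 TPM. B2m, the invariant chain, rose by 2.02 ± 0.23 (SE, adjusted p = 5.5e-07). Of 12 NK cell ligands 6 rose and 0 fell (adjusted over the list alone, 7 and 1), including Clec2d (1.38 ± 0.25, SE), while Raet1e, a ligand of the activating receptor NKG2D, rose by 1.17 ± 0.25 (SE) and did not pass without parental replicate 3 (1.02, adjusted p = 0.050). Checkpoint ligands rose in 3 of 11 genes, with Cd274, which encodes PD-L1, at 18.1 ± 7.85 against 3.20 ± 0.832 TPM (SD; log2 difference 2.08) and Lgals9 at 1.60 ± 0.29 (SE), while the call of Tnfrsf14 (0.57) was lost without parental replicate 1, 2 or 3 (adjusted p = 0.080, 0.10 and 0.28) and without several late lines. 0 of the 3 MHC class II genes tested passed in limma (median 0.63). The NK cell ligand list shares H2-K1, H2-D1 and H2-T23 with the MHC class I list, so these lists are not independent.

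Beyond interferon genes, the largest rises were in Mcoln3, a lysosomal calcium channel gene (5.28 ± 1.14, SE, adjusted p = 0.0028; 66.1 ± 38.3 against 0.413 ± 0.447 TPM, SD), Ucp2, a mitochondrial carrier (4.36 ± 0.66, SE), Art5 (4.17 ± 0.54, SE), Slc4a5 (4.14 ± 0.93, SE), the melanocortin receptor accessory gene Mrap (4.12 ± 0.45, SE) and Tlcd2 (3.99 ± 0.38, SE). Spp1, which encodes osteopontin, rose by 3.34 ± 0.68 (SE) to 170 ± 147 TPM (SD). The largest falls were in Gxylt2 (-4.13 ± 0.75, SE; 4.77 ± 5.88 against 68.0 ± 4.15 TPM, SD), the transcriptional cofactor Vgll3 (-3.45 ± 0.71, SE), the myelin gene Pmp22 (-3.31 ± 0.34, SE), the gap junction gene Gjc1 (-3.31 ± 0.44, SE), Igsf3 (-3.19 ± 0.28, SE) and Nnmt (-3.15 ± 0.59, SE). The N-cadherin gene Cdh2 fell by 0.93 (adjusted p = 0.00077), the chemokine receptor Ackr3 by 1.64 (adjusted p = 5.0e-05) and the YAP target Amotl2 by 1.12 (adjusted p = 0.0041).

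Of 30 proliferation genes 1 fell and 0 rose, and 0 passed when adjusted over the list alone; the list median was -0.79. Its member Ccnd1 differed by -1.57 ± 0.50 (SE, adjusted p = 0.038), with adjusted p = 0.16 without parental replicate 3, 0.19 without replicate 1 and 0.074 without replicate 2. Melanocyte differentiation had 1 riser of 19, and Pmel (-0.00, adjusted p = 1) and Mitf (-0.25, adjusted p = 0.69) did not pass. In neural crest genes 1 rose and 1 fell of 9, with a median of -0.20 and a mean of 0.02. Mesenchymal and matrix genes fell in 3 of 21, YAP targets in 2 of 13, oxidative phosphorylation genes in 2 of 27 and fibroblast markers in 1 of 4 (Pdgfrb; the list median was 0.22 and the test pointed down). Stress genes rose in 1 of 22 and fatty acid genes went each way in 1 of 24. Chemokines and lymphangiogenic factors rose in 2 of 10 and fell in 1. Lymphocyte markers rose in 1 of 3, namely Lck (1.73 ± 0.31, SE; 5.25 ± 1.87 TPM, SD), and myeloid markers in 1 of 3. Many of these calls needed all 3 parental cultures, although the log2 differences changed little, as for Gpnmb (0.53; 0.61, 0.52 and 0.47 without replicate 1, 2 and 3). Without parental replicate 3 the call was lost for Gpnmb (adjusted p = 0.25), Erbb3 (0.20), Yap1 (0.057), Col1a2 (0.21), Thbs1 (0.17), Arhgef17 (0.092), Uqcrc1 (0.088), Cox7a2 (0.17), Pdgfrb (0.076), Zfp36 (0.12), Acox1 (0.15), Ldlr (0.065) and Cd14 (0.072). Each of these 13 genes also lost its call without replicate 1 or replicate 2, at adjusted p from 0.051 (Cd14 without replicate 1) to 0.20 (Thbs1 without replicate 2), as did Cxcl10 without replicate 1 (0.061). The calls of Cdh2, Amotl2, Ackr3, Spp1 and Lck held without each library in turn. 0 of 25 hypoxia genes (median 0.24) and 0 of 1 endothelial and epithelial marker passed in limma.

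In total 860 genes rose and 609 fell of 14194 tested (3773 had an unadjusted p under 0.05), of which 304 and 157 differed by at least 2-fold. The numbers were 1049 and 1050 with median-of-ratios scaling and 729 and 814 without a filter on low values. They were 1061 and 1273 with library set (below) as a covariate and 490 and 662 in set 1 and 41 and 21 in set 2 alone, so which direction held more genes depended on these choices. In camera, 7 lists passed, and interferon-stimulated genes (adjusted p = 0.0166), interferon-gamma and GTPase genes (0.0166) and MHC class I (0.0278) also passed with an estimated correlation. NK cell ligands (adjusted p = 0.104 with an estimated correlation), signalling components (0.122), proliferation (0.515) and YAP targets (0.522) did not. The number of genes depended on single parental cultures, with 767, 774 and 435 genes without parental replicate 1, 2 and 3. The generation libraries fell into 2 sets of 16 by the level of 1 abundant predicted transcript, and within the sets alone the medians were 1.74 and 1.89 for interferon-stimulated genes and 1.16 and 1.00 for MHC class I.

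**Figure D1:**
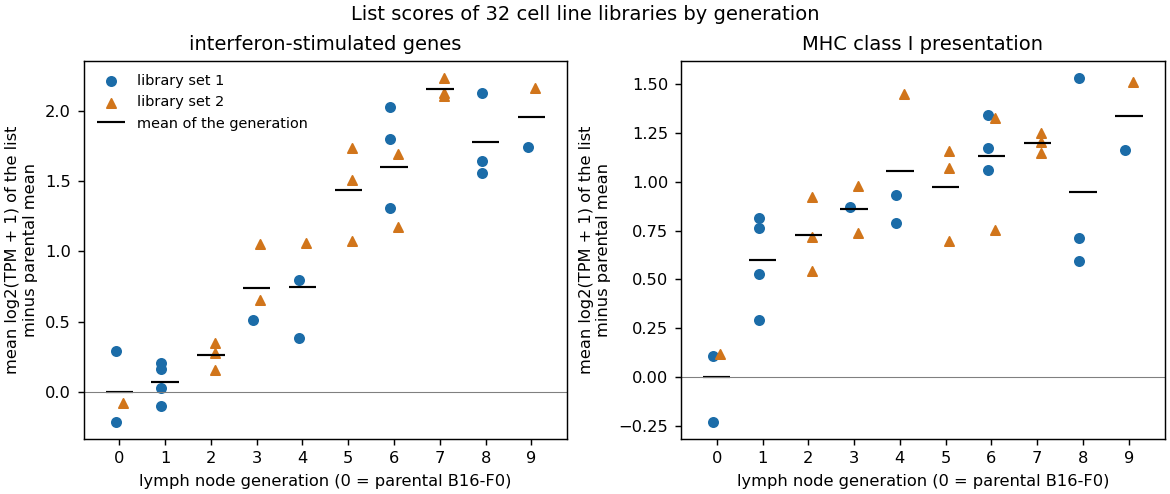
List scores (mean log2(TPM + 1) minus the parental mean) of interferon-stimulated genes and MHC class I genes in each library by generation, with parental cells at generation 0, symbols for the library sets and lines at generation means. The mean interferon-stimulated score went from 0.07 at generation 1 to 1.96 at generation 9.

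Late lines (n = 13) were next set against early lines (n = 10), which asks what is acquired between the early and the late rounds of passage. Interferon-stimulated genes again led: 42 of 45 rose and 0 fell (43 rose when adjusted over the list alone), with a median log2 difference of 1.36. Rtp4 rose from 4.54 ± 4.95 to 61.6 ± 28.1 TPM (SD), a log2 difference of 3.71 ± 0.39 (SE, adjusted p = 1.0e-07), and the ubiquitin-like modifier Isg15 from 19.4 ± 11.2 to 122 ± 47.2 TPM (2.58 ± 0.27, SE). Xaf1 rose by 2.62 ± 0.27 (SE) and Mx2 by 2.00 ± 0.19 (SE). In the interferon-gamma and GTPase list 12 of 17 genes rose and 0 fell, with a median of 1.19; Igtp rose by 2.38 ± 0.19 (SE, adjusted p = 8.2e-10) and Gbp3 by 2.27 ± 0.27 (SE). Signalling components rose in 9 of 21, with Stat1 going from 30.6 ± 7.7 to 96.8 ± 22.4 TPM (SD) and Stat2 rising by 1.26 ± 0.16 (SE). Lymphocyte markers rose in 2 of 3, namely Lck (0.61 ± 0.20, SE, adjusted p = 0.044) and Coro1a (0.68 ± 0.22, SE, adjusted p = 0.036), but both calls were lost with some single libraries left out, as without LN1 replicate 4 (adjusted p = 0.088 and 0.062). Myeloid markers rose in 0 of 3.

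MHC class I genes divided, as 10 rose and 3 fell of 22 (adjusted over the list alone, 15 and 3). The 3 that fell were the endoplasmic reticulum chaperone genes Pdia3 (-0.72, adjusted p = 0.0051), Canx (-0.38, adjusted p = 0.015) and Calr (-0.57, adjusted p = 0.048), named after their values were seen. B2m rose by 0.95 ± 0.15 (SE, adjusted p = 8.3e-05), the immunoproteasome gene Psmb9 by 1.35 ± 0.23 (SE) and the peptide transporter Tap1 by 0.85 ± 0.15 (SE), while H2-D1 rose by 0.49 (adjusted p = 0.015) and H2-K1 did not pass at 0.55 (adjusted p = 0.082; 0.048 without LN3 replicate 2). Cd274 rose from 6.43 to 18.1 TPM (log2 difference 1.32 ± 0.21, SE, adjusted p = 0.00010) and Lgals9 by 1.23 ± 0.19 (SE), whereas Tnfsf9, the ligand of 4-1BB, fell by 0.79 (adjusted p = 0.00030); in total 2 checkpoint ligands rose and 1 fell of 11. NK cell ligands rose in 4 of 12, with Clec2d at 1.12 ± 0.17 (SE). Ccl5 differed by 1.07 (adjusted p = 0.042) and did not pass when any of 12 libraries was left out, as with adjusted p = 0.066 without LN1 replicate 4.

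Hypoxia and glycolysis genes fell in 4 of 25 and rose in 0 (7 fell when adjusted over the list alone), with P4ha2 at -1.16 ± 0.27 (SE), Ero1l at -1.36 ± 0.32 (SE), Vegfa at -1.18 ± 0.36 (SE) and Pkm at -0.41 ± 0.11 (SE). The proliferation gene Ccnd1 fell from 65.2 to 25.4 TPM (-1.53 ± 0.33, SE, adjusted p = 0.0021), as 1 of 30 in its list. YAP targets fell in 2 of 13, namely Cyr61 (-1.19 ± 0.27, SE) and Arhgef17 (-0.57 ± 0.14, SE), and the matrix gene Sparc fell from 439 to 283 TPM. The chaperone Hspa5 fell by 0.79 (adjusted p = 0.017). Sox10 rose by 0.37 (adjusted p = 0.014) while Mitf and Pmel did not pass. Vgll3 (-3.21 ± 0.47, SE), Tmem98 (-2.09 ± 0.35, SE), Gxylt2 (-2.04 ± 0.49, SE) and Kdelr3 (-1.92 ± 0.35, SE) had among the largest falls, and Tlcd2 (2.79 ± 0.25, SE), Mcoln3 (3.05 ± 0.75, SE) and the myosin light chain gene Myl9 (2.70 ± 0.62, SE) rose. The cystine transporter gene Slc7a11 fell by 2.09 (adjusted p = 0.029; 0.055 without LN1 replicate 4). Rn7s1 and Rn7s2 gave identical values, and reads of such near-identical copies cannot be assigned with certainty.

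There were 1297 genes that rose and 569 that fell, 130 and 55 of them by at least 2-fold. With median-of-ratios scaling the numbers were 1073 and 1211, so the share of risers depended on the scaling. Of 10 lists that passed in camera, interferon-stimulated genes (adjusted p = 0.0115) and interferon-gamma and GTPase genes (0.0121) passed with an estimated correlation, and hypoxia (0.343), MHC class I (0.343), stress genes (0.310), YAP targets (0.343) and proliferation (0.669) did not. The interferon-stimulated median was 1.44 and 1.26 within the library sets.

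Early lines (n = 10) against parental cells (n = 3) asks what is present after the earliest passages. MHC class I rose in 4 of 22 genes (8 when adjusted over the list alone) and fell in 0, with a median log2 difference of 0.54. H2-D1 rose from 83.2 ± 19.9 to 215 ± 39.8 TPM (SD; 1.36 ± 0.21, SE, adjusted p = 0.00044) and the nonclassical gene H2-M3 by 1.85 ± 0.25 (SE, adjusted p = 5.6e-05). H2-K1 rose by 2.00 ± 0.34 (SE, adjusted p = 0.0013; 0.063 without parental replicate 3) and B2m by 1.07 ± 0.24 (SE, adjusted p = 0.027; 0.44 without parental replicate 3 and 0.19 without replicate 2). Interferon-stimulated genes had a median of 0.25, and 1 of 45 rose (4 when adjusted over the list alone); Stat1 did not pass (0.23, adjusted p = 0.73). The AP-1 family gene Batf rose by 2.14 ± 0.22 (SE, adjusted p = 6.1e-07) to 12.3 TPM. Igsf3 fell by 2.63 (adjusted p = 8.1e-07), Pmp22 by 2.64 (adjusted p = 4.4e-05), the integrin gene Itgb5 by 2.47 (adjusted p = 6.1e-07) and the syndecan Sdc3 by 2.15 (adjusted p = 4.4e-05). Of 25 hypoxia genes 0 passed over all genes and 11 rose when adjusted over the list alone (median 0.68). Among NK cell ligands 2 of 12 rose, and among chemokines 1 rose and 1 fell, the latter being Ackr3 (-1.45 ± 0.26, SE, adjusted p = 0.0030; 0.067 without parental replicate 3).

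The early difference held 28 risers and 30 falling genes (1623 with an unadjusted p under 0.05), or 57 and 36 with median-of-ratios scaling, 70 and 14 with a pseudocount of 0.1, 26 and 122 without a filter, and 14 genes in total without parental replicate 3 and 25 without replicate 2. Camera with an estimated correlation gave adjusted p = 0.0587 for MHC class I, 0.268 for hypoxia and 0.528 for interferon-stimulated genes. Within the library sets the MHC class I medians were 0.55 and 0.47, and the interferon-stimulated medians 0.05 and 0.39.

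Over generations 1 to 9 (29 lines), the slope of each gene asks which levels move steadily with passage. Interferon-stimulated genes had a median slope of 0.26 log2 units per generation, with 42 of 45 rising. Usp18 rose by 0.63 ± 0.06 per generation (SE, adjusted p = 4.3e-09), Irf7 by 0.46 ± 0.04 (SE), Stat1 by 0.29 ± 0.03 (SE), B2m by 0.17 ± 0.03 (SE) and Cd274 by 0.26 ± 0.03 (SE). Mcoln3 (0.58 ± 0.13, SE) and Myl9 (0.53 ± 0.10, SE) also rose; Vgll3 (-0.54 ± 0.09, SE), Kdelr3 (-0.36 ± 0.06, SE) and Ccnd1 (-0.22 ± 0.06, SE) fell. Across all genes 1147 rose and 531 fell, or 941 and 1089 with median-of-ratios scaling. Interferon-stimulated genes (adjusted p = 0.00364) and interferon-gamma and GTPase genes (0.0118) passed camera with an estimated correlation, and MHC class I did not (0.403).

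**Figure D2:**
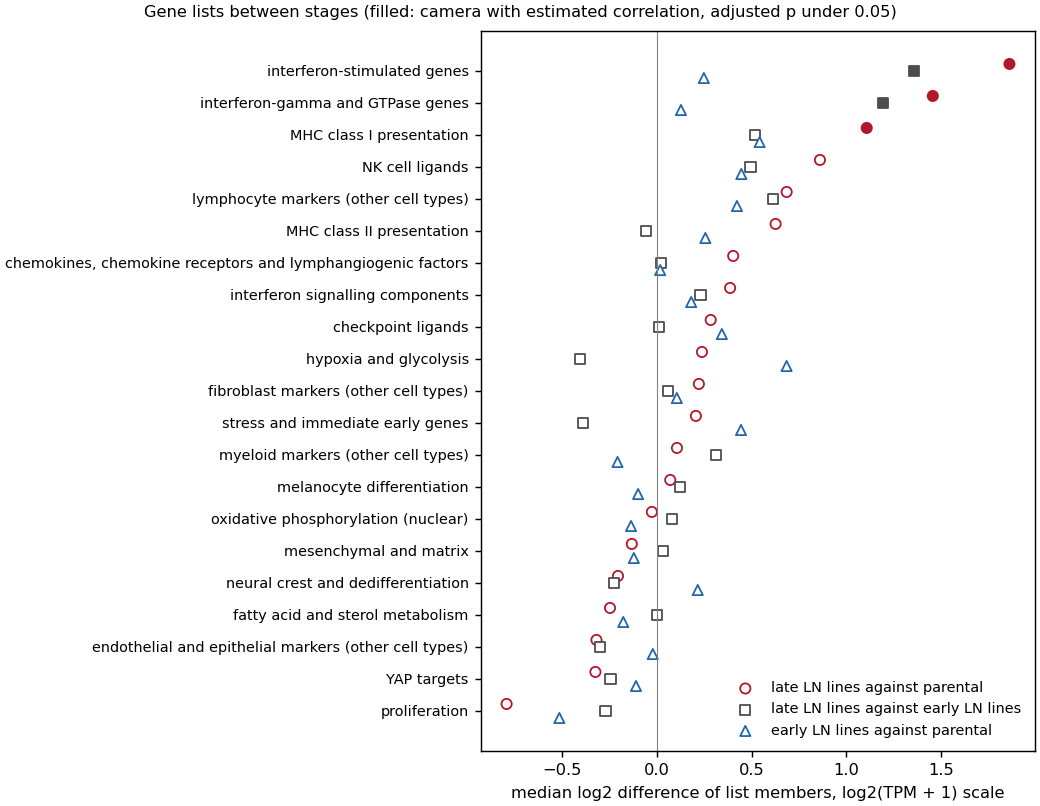
Median log2 difference of each gene list for late against parental (red circles), late against early (black squares) and early against parental (blue triangles), with filled markers where camera with an estimated correlation gave an adjusted p under 0.05. Interferon-stimulated genes stood at 1.86, 1.36 and 0.25.

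The guide libraries ask how much of the difference between B16-F0 and LN6-987AL remains when interferon receptors or Stat1 are targeted, with 1 library per line and guide. Stat1 itself was at 18.0 TPM with sgLacZ and 2.79 TPM with sgStat1 in B16-F0, and at 80.9 and 3.79 TPM in LN6-987AL. Ifnar1 went from 35.9 to 17.3 TPM with sgIfnar1 in B16-F0 and from 42.8 to 25.4 TPM in LN6-987AL. Ifngr1 went from 15.3 to 11.1 TPM with sgIfngr1 in B16-F0 and from 17.6 to 13.5 TPM in LN6-987AL. In B16-F0 with both receptor guides Ifnar1 was at 15.3 and Ifngr1 at 10.2 TPM. NBF0IFNRKOLN1, whose name points to an interferon receptor knockout B16-F0 line recovered from a lymph node, had Ifnar1 at 24.5 and 11.8 TPM and Ifngr1 at 13.3 and 6.66 TPM in its 2 libraries. RNA level does not measure editing, since edited transcripts may still be counted.

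Across the 4 guide pairs, LN6-987AL had 2710 genes above B16-F0 and 1955 below, of 12795 tested, or 2394 and 2297 with median-of-ratios scaling. The 4 pairs came from 1 LN6-987AL line and 1 B16-F0 line. The SE and adjusted p-values therefore measure spread between libraries of these lines, not between lymph node lines. Interferon-stimulated genes rose in 21 of 39 with 0 falling (27 when adjusted over the list alone; median 1.37), although receptor and Stat1 guides are among the pairs. MHC class I rose in 10 of 22 and fell in 1, with H2-K1 at 151 ± 66.6 against 32.7 ± 7.08 TPM (SD; 2.09 ± 0.17, SE) and H2-M3 at 1.87 ± 0.12 (SE). Cd274 (1.28 ± 0.14, SE, adjusted p = 0.0021), the class I activator Nlrc5 (1.77, adjusted p = 0.0049), Ccl5 (1.97 ± 0.18, SE), Raet1e (1.43 ± 0.06, SE) and Ulbp1, another NKG2D ligand (3.32 ± 0.20, SE; 45.2 against 3.44 TPM), were higher. The meiotic gene Sycp3 (5.69 ± 0.24, SE; 64.1 ± 4.14 against 0.336 ± 0.599 TPM, SD), Slc4a5 (5.35 ± 0.18, SE), Mcoln3 (4.93 ± 0.20, SE), Mbp (3.29 ± 0.15, SE) and Spp1 (2.72 ± 0.15, SE) were also higher. The receptor tyrosine kinase Kit rose by 2.08 ± 0.17 (SE) and fibronectin Fn1 by 1.98 ± 0.14 (SE). Gxylt2 fell by 3.97 (adjusted p = 0.00022), Evl, an actin regulator, by 3.57 (adjusted p = 0.00015) and Igsf3 by 3.44 (adjusted p = 0.00015), and Tmem98 was listed at 0 in LN6-987AL.

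Other lists of the line difference were mixed. Proliferation fell in 12 of 30 genes and rose in 1, with Mcm6 at -0.60 ± 0.06 (SE) and Rrm2 at -0.65 (adjusted p = 0.0039). Interferon-gamma and GTPase genes rose in 9 of 13, signalling components in 13 of 20 with 1 falling, NK cell ligands in 5 of 10, chemokines in 5 of 11 with 1 falling, and stress genes in 8 of 21 with 1 falling, among them Atf3 (1.02, adjusted p = 0.0019). Melanocyte genes rose in 7 of 19 and fell in 2. Checkpoint ligands rose in 3 of 8 and fell in 2, with Cd276 at -1.18 ± 0.15 (SE). Matrix genes fell in 7 of 19 and rose in 4. Of 24 hypoxia genes 3 fell and 1 rose, with P4ha2 at -1.32 ± 0.11 (SE). Fatty acid genes rose in 6 of 24 and fell in 2, oxidative phosphorylation genes in 4 and 3 of 26, and YAP targets in 2 and 4 of 13. Mitochondrial transcripts, which only this table holds, passed in 0 of 15 in limma (median 0.00). All 6 lists that passed camera had an adjusted p = 0.894 with an estimated correlation. With a guide pair left out the genes numbered 2677 without sgIfnar1, 2726 without sgIfngr1 and 2940 without sgStat1. Without the LN6-987AL library, 852 genes tested in both tables rose in late lines against parental. Of these, 672 were also higher in the guide table, where chance gives 184 for independent calls. Of 519 that fell, 415 were lower, where chance gives 80.8. Both comparisons have B16-F0 as their reference, and LN6-987AL came from the same serial passage as the other late lines. The overlap is therefore no independent replication.

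By guide, the median line difference over 40 interferon-stimulated genes was 2.36 log2 units with sgLacZ, 1.90 with sgIfngr1, 0.46 with sgIfnar1 and 0.37 with sgStat1. In LN6-987AL, sgIfnar1, sgStat1 and sgIfngr1 gave the list medians of -2.10, -2.12 and -0.36 against sgLacZ, each below all 10000 random lists, and 39 of 40 genes were lower with sgIfngr1. In B16-F0 the medians were -0.28, -0.29 and 0.14 in the same order. Other lists moved too in LN6-987AL against the same sgLacZ library, in that order by -0.28, -0.08 and -0.26 for hypoxia, -0.24, -0.16 and -0.25 for stress, -0.30, -0.15 and -0.24 for fatty acid genes and 0.13, 0.28 and 0.48 for mitochondrial transcripts. With sgIfnar1 and sgIfngr1 the hypoxia and fatty acid medians were below all 10000 random lists too. Changes of that size cannot be tied to interferon from 1 sgLacZ library. The same limit holds for the sgIfngr1 medians of interferon-stimulated genes (-0.36) and MHC class I genes (-0.38). Isg15 in LN6-987AL was at 121 TPM with sgLacZ, 72.4 with sgIfngr1, 8.90 with sgIfnar1 and 8.71 with sgStat1, and B2m at 2355, 1773, 623 and 738 TPM in that order. H2-K1 kept part of its level, at 240 TPM with sgLacZ and 83.6 and 123 TPM with sgIfnar1 and sgStat1, against 41.7 TPM in B16-F0 with sgLacZ. MHC class I medians in LN6-987AL were -0.95 with sgIfnar1, -0.85 with sgStat1 and -0.38 with sgIfngr1. Ifi27 was at 630 TPM with sgLacZ and 58.4 and 53.0 TPM with sgIfnar1 and sgStat1 in LN6-987AL, but at 48.2, 24.7 and 32.8 TPM in B16-F0. The proliferation list was higher with each guide in LN6-987AL, by 0.18 (sgStat1), 0.27 (sgIfnar1) and 0.20 (sgIfngr1), but the 3 values share 1 sgLacZ library and are not independent, and in B16-F0 they were 0.01, -0.10 and -0.04.

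Tested over both lines as replicates, limma called 0 genes for sgStat1, sgIfnar1 and sgIfngr1, where 692, 996 and 563 genes had an unadjusted p under 0.05. Stat1 differed by -3.21 ± 0.46 (SE, adjusted p = 0.44) with sgStat1 and Ifnar1 by -0.87 ± 0.10 (SE, adjusted p = 0.16) with sgIfnar1, in an additive fit that counts unequal effects in the 2 lines as spread. For sgStat1, 3 genes were called without the B16-F0 sgStat1 library and 1 without the LN6-987AL one, and 1 for sgIfngr1 without the LN6-987AL one. Camera gave interferon-stimulated genes a median of -1.16 (adjusted p = 1.2e-19) for sgStat1, -1.20 (3.4e-15) for sgIfnar1 and -0.08 (0.961) for sgIfngr1, and adjusted p = 0.687 and 0.693 with an estimated correlation for sgStat1 and sgIfnar1.

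NBF0IFNRKOLN1 was compared with B16-F0 carrying both receptor guides. Interferon-stimulated genes had a median of -0.00 at percentile 29.4 of random lists, MHC class I a median of 0.37 with 17 genes higher and 5 lower, and NK cell ligands 0.72 with 9 higher and 1 lower, both above all random lists. Hypoxia (0.48) and stress genes (0.35) were also above all random lists, and proliferation (-0.69, with 0 of 30 genes higher) was below all. Against B16-F0 sgLacZ the MHC class I medians of its 2 libraries were smaller, at 0.17 and 0.08, and those of NK cell ligands differed, at 0.68 and 0.06. The hypoxia medians also differed between its libraries, at 0.49 and 0.11, as did those of stress genes, at 0.49 and 0.01. H2-K1 was at 69.7 and 59.8 TPM in its 2 libraries, 26.3 TPM with both guides and 41.7 TPM with sgLacZ. Proliferation stood at -0.76 against B16-F0 sgLacZ, and its 2 libraries differed (-1.48 and -0.04).

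**Figure D3:**
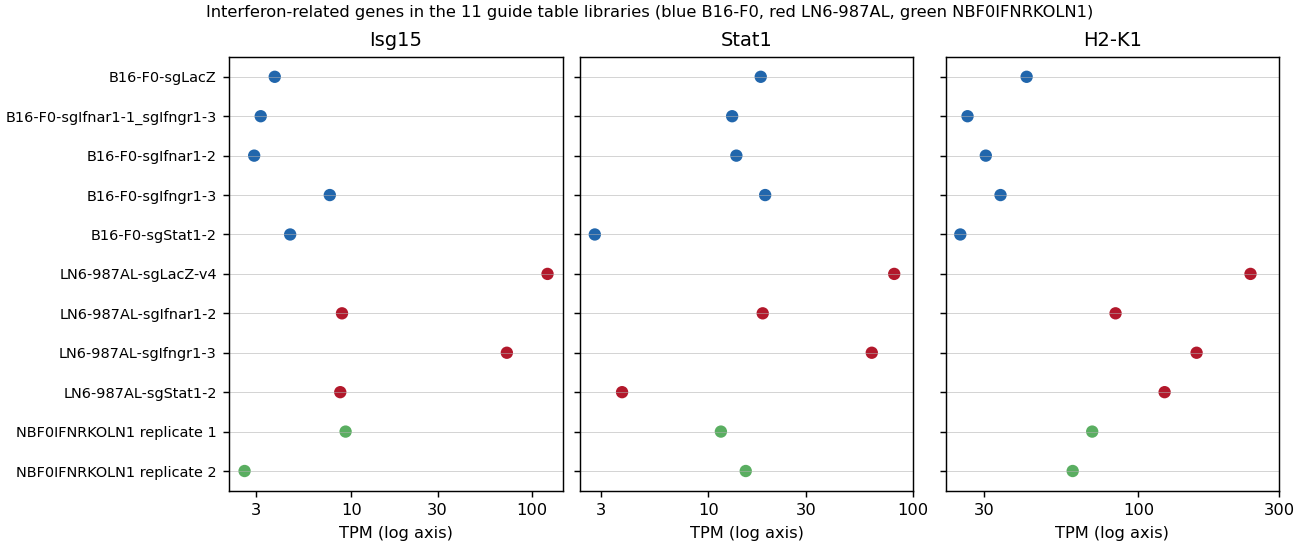
TPM (log axes) of Isg15, Stat1 and H2-K1 in the 11 guide libraries, with B16-F0 in blue, LN6-987AL in red and NBF0IFNRKOLN1 in green. Isg15 in LN6-987AL stood at 121 TPM with sgLacZ and 8.71 TPM with sgStat1.

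The lymph node libraries ask how node cells differ between tumour-naive mice and mice bearing B16-F0 or LN6-987AL. After filtering, 8626, 9958 and 8806 cells remained, and values follow in the order tumour-naive, B16-F0 and LN6-987AL. B-like cells were 35.7% (34.7% to 36.8%), 45.1% (44.1% to 46.1%) and 48.8% (47.8% to 49.9%) of cells. CD4 T-like cells were 21.3% (20.5% to 22.2%), 13.7% (13.04% to 14.4%) and 12.7% (11.97% to 13.4%). CD8 T-like cells were 20.2% (19.4% to 21.1%), 17.7% (16.97% to 18.5%) and 14.4% (13.7% to 15.2%). Regulatory T-like cells were 3.802%, 3.75% and 3.30% of all cells, and 15.1% (13.7% to 16.7%), 21.5% (19.6% to 23.5%) and 20.7% (18.6% to 22.9%) of CD4 and regulatory T-like cells together. Gamma delta or innate lymphoid-like cells were 1.63% (1.38% to 1.92%), 0.592% (0.451% to 0.764%) and 0.4656% (0.334% to 0.631%). Mature dendritic-like cells were 2.93%, 1.84% and 2.31%, macrophage-like cells 1.17%, 1.21% and 1.49%, NK-like cells 0.394%, 0.512% and 0.363%, plasmacytoid dendritic-like cells 0.498%, 0.372% and 0.4997%, and stromal-like cells 0.255%, 0.221% and 0.284%. Neutrophil-like cells numbered 0, 14 and 6, and 0 of the tumour-naive cells allows a share of up to 0.0348% (3 counts of the total). Melanoma-like cells were 0.267%, 0.321% and 0.522%, which is taken up below with the melanocyte UMIs. Unnamed clusters held 11.8%, 14.4% and 14.7%, and shares sum to a whole, so a rise in B-like cells lowers the others. The share of cells with Cd79a after thinning was 45.7%, 57.4% and 62.1%, against 2.24%, 3.69% and 4.57% in CD8 T-like cells, and that with Foxp3 1.98%, 1.59% and 1.199%, against 0.131%, 0.0903% and 0.0470% in B-like cells.

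**Figure D4:**
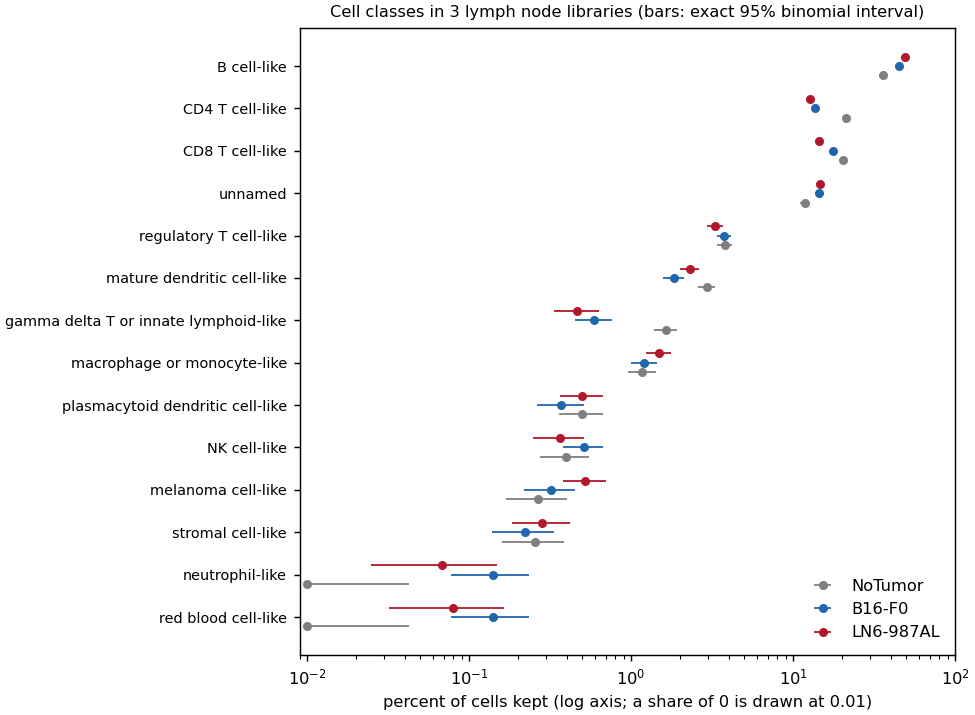
Percent of cells in each named class in the 3 lymph node libraries, with exact 95% intervals for counting error. B-like cells were at 35.7%, 45.1% and 48.8%, and all 45 barcodes with at least 10 melanocyte UMIs in the other 2 libraries coincided with barcodes of melanoma cells in the LN6-987AL library.

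Interferon-stimulated genes were at 2796, 3211 and 3628 CPM in B-like cells, a ratio of 1.297 (1.28 to 1.31) for LN6-987AL over tumour-naive and 1.13 (1.12 to 1.14) over B16-F0. In CD4 T-like cells the ratios were 1.26 (1.24 to 1.28) and 1.21 (1.19 to 1.24), in CD8 T-like cells 1.199 (1.18 to 1.22) and 1.13 (1.12 to 1.15), and in regulatory T-like cells 1.46 (1.43 to 1.503) and 1.24 (1.21 to 1.27), with the list median above all 10000 random lists each time. Ifit3 in B-like cells was at 5.98, 12.6 and 36.7 CPM, a ratio of 6.14 (4.90 to 7.76) for LN6-987AL over tumour-naive. Clusters made up these classes in different proportions in the 3 libraries, which adds to the class ratios. Within the 4 B-like clusters not led by interferon-stimulated genes, the list ratios for LN6-987AL over tumour-naive were 1.15, 1.15, 1.17 and 1.15, and the list was at 2610, 2949 and 2995 CPM in the largest of these, so B16-F0 and LN6-987AL differed less there than in the class. Of the Ifit3 UMIs in B-like cells of the LN6-987AL library, 591 were in the cluster that such genes led, where the list ratio was 1.07, and from 9 to 33 in each of the other 4. In the main CD4 T-like cluster the list ratio was 1.19 (1.17 to 1.21). Ifit3 was at 7.66, 7.81 and 27.1 CPM in CD4 T-like cells and 14.6, 17.2 and 38.9 CPM in CD8 T-like cells. In the main CD4 T-like cluster it was at 4.68, 6.15 and 13.1 CPM, and of the Ifit3 UMIs in CD4 T-like cells of the LN6-987AL library 80 were there and 102 in a small cluster led by interferon-stimulated genes. Isg15 in regulatory T-like cells was at 28.6, 57.6 and 107 CPM, a ratio of 3.75 (2.87 to 4.96). Interferon-gamma and GTPase genes had ratios over tumour-naive of 1.26 in CD4 T-like and 1.07 in B-like cells, and MHC class I genes 0.993, 0.940 and 1.03 in CD4 T-like, CD8 T-like and B-like cells.

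Regulatory T-like cells had Foxp3 at 288, 212 and 177 CPM, a ratio of 0.614 (0.544 to 0.694) for LN6-987AL over tumour-naive, and Il2ra at 309, 196 and 166 CPM, while Ctla4 was at 203, 334 and 234 CPM, Lag3 at 22.04, 70.2 and 48.4 CPM and Gzmb at 11.8, 19.4 and 36.8 CPM. Their Treg genes summed to 4527, 4407 and 4416 CPM, T cell checkpoint and exhaustion genes to 594, 789 and 697 CPM and proliferation genes to 422, 623 and 521 CPM. CD8 T-like cells had Ccl5 at 41.8, 49.1 and 82.9 CPM and Ly6c2 at 217, 270 and 359 CPM, but Cxcr6 at 125, 130 and 89.9 CPM. Naive T cell genes in these cells summed to 3897, 4690 and 4185 CPM and T and NK effector genes to 1461, 1683 and 1641 CPM. An unnamed cluster with CD8 T cell markers, which had the effector genes Cxcr3 and Eomes among its top genes, is not in these CD8 T-like values. CD4 T-like cells had the chemokine Xcl1 at 4.58, 9.67 and 24.3 CPM and Cxcr4 at 12.2, 72.6 and 24.7 CPM. B-like cells had Cd86 at 29.9, 55.0 and 46.6 CPM and Cd69 at 250, 338 and 328 CPM; B cell activation genes had a ratio of 1.10 and dendritic cell maturation genes 0.981 for LN6-987AL over tumour-naive. The heat shock gene Hsph1 was lower with LN6-987AL in B-like cells (42.3, 40.1 and 15.6 CPM) and CD8 T-like cells (58.5, 50.2 and 26.03 CPM), and stress genes had ratios of 0.915 and 0.819. Free RNA limits some values: Ptgds, a leading gene of the melanoma-like cluster, had 2, 0 and 110 UMIs in B-like cells, and the haemoglobin gene Hbb-bs had 24, 1227 and 655 UMIs where red blood cell-like barcodes numbered 0, 14 and 7. MHC class II genes, which B cells express highly, had ratios over tumour-naive of 1.35 in CD4 T-like cells for LN6-987AL and 1.34 for B16-F0. In regulatory T-like cells they were at 3058, 2940 and 4691 CPM, ratios of 1.53 for LN6-987AL and 0.962 for B16-F0, whereas the interferon-stimulated ratio for B16-F0 in that class was 1.18 (1.15 to 1.22).

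**Figure D5:**
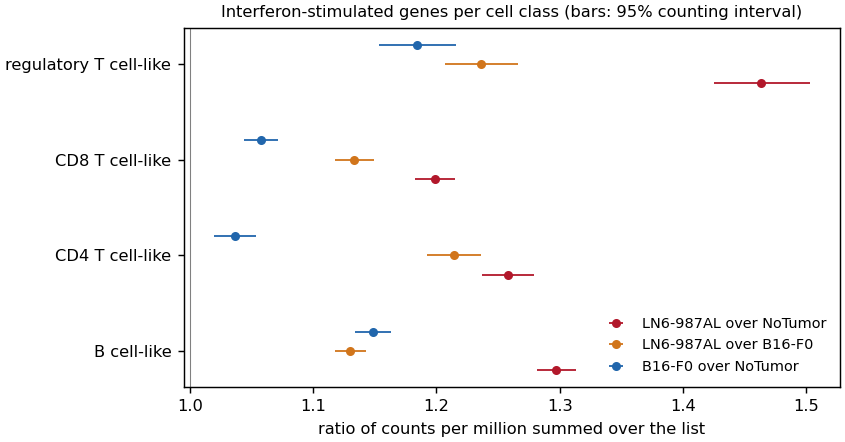
Ratios between the 3 lymph node libraries of the CPM summed over interferon-stimulated genes in 4 cell classes, with 95% counting intervals. The highest ratio, for LN6-987AL over tumour-naive (NoTumor) in regulatory T-like cells, was 1.46.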

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

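The tests of explanations in this part were chosen only after the results were seen, as were the division into library sets and the look at Xist. The splits of libraries for the interferon-stimulated medians were also added after those medians were seen, but what they would show was written down before they were computed.

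List scores and 9 fixed genes were tested within generation 1, generation 6, early and intermediate lines, in groups of 4 to 10 libraries. Of 116 such tests, 9 found a library far from the others of its group, and chance gives about 1 in 20. Generation 1 lines are among the early lines and some genes are in more than 1 list, so the tests are not independent. Of the generation 1 lines, LN1-16IL had the lowest hypoxia score, 0.054 against 0.74 for the next line, and the lowest chemokine score, -0.015 against 0.32. In generation 6, LN6-991AL had the lowest NK cell ligand score (0.49, next 0.91) and LN6-877AL the highest hypoxia score (0.91, next 0.17). LN3-392AL was the lowest early line in oxidative phosphorylation (-0.45, next -0.17) and the highest in fibroblast markers (0.66, next 0.12). Of the intermediate lines, LN4-533BL was highest in lymphocyte markers (1.64, next 0.90), LN5-809CL in myeloid markers (0.98, next 0.03) and LN5-716BR in Pmel (12.54 in log2(TPM + 1), next 12.18).

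Some guides moved a list in opposite directions in the 2 lines; each line and guide had 1 library, so these differences were not tested. With sgIfngr1 the interferon-stimulated genes differed from sgLacZ by 0.14 in B16-F0 and -0.36 in LN6-987AL, a difference of -0.50, and MHC class I genes by 0.13 and -0.38, also a difference of -0.50. Mitochondrial transcripts differed between the lines by 0.69 with sgIfngr1 (-0.21 and 0.48) and by 0.45 with sgStat1 (-0.17 and 0.28). With sgIfnar1 hypoxia genes differed by -0.40 (0.12 and -0.28) and stress genes by -0.30 (0.06 and -0.24).

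The lymph node library from mice bearing LN6-987AL held 29 barcodes with at least 50 melanocyte UMIs, 0.287% (0.193% to 0.412%, exact) of its barcodes, with a median of 147427 UMIs. The tumour-naive and B16-F0 libraries held 0 such barcodes, which allows shares of up to 0.0302% and 0.0265% (3 counts of the total). Yet they had 469 and 439 melanocyte UMIs (Pmel 208 and 217) against 73044 in the LN6-987AL library. Melanoma cells in those nodes would bring barcodes of their own, and 0 of the 45 barcodes with at least 10 such UMIs were other than LN6-987AL melanoma-cell barcodes. The melanoma-like cluster held 23 tumour-naive, 32 B16-F0 and 46 LN6-987AL cells. Barcodes with at least 10 such UMIs numbered 22 in the tumour-naive and 23 in the B16-F0 library. Some cells of this cluster thus had fewer, and for these the source was not tested. Molecules of the LN6-987AL library counted in the other libraries are a candidate source, since 100% of the 45 barcodes were LN6-987AL melanoma-cell barcodes, while 0.620% of all barcodes are shared.

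Interferon-stimulated genes were higher in late lines than in parental cells by a median log2 difference of 1.86. The highest of 99 other splits gave 1.31, so 1 of 100 splits, the real one, reached 1.86. Against early lines 1 of 100 splits reached 1.36, and the highest other gave 0.54. The splits argue against a random division of independent libraries. They cannot exclude differences that related lines came to share by chance. The tables argue against the library set as the whole cause, since the median was 1.80 with the set in the fit. RNA of lymph node lymphocytes in the late lines is also argued against. At the highest share of lymph node RNA that any of 13 lymphocyte markers allows (1.70%), such RNA brings 2.70% of the summed rise of 2076 TPM. These markers set no limit for stromal or myeloid cells, whose RNA was not tested here. In the guide table, 19.6% of the line difference in these genes was left with sgIfnar1 in both lines, which is consistent with interferon receptor signalling in the cultured cells as a hypothesis. Which ligand acts, and whether the lines were selected or changed state, was not tested.

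Xist, the RNA of the inactive X chromosome, was above 0.3 TPM in 8 of 13 late lines, in LN4-521BL (0.316 TPM) of the 6 intermediate lines and in 0 early lines; the late mean was 0.794 TPM and the highest parental or early value 0.0242 TPM. RNA of female lymph node leukocytes is argued against, since lymphocyte markers stood at a median of 0.0448 times the level that Xist would need; Ptprc was at 0.0380 TPM and would need to be at 0.847 TPM. The library set is argued against as well, as the smaller of the late minus early differences within the sets was 0.60 (log2). RNA of stromal cells may contribute and cannot be told apart, because 0 of 12 fibroblast markers would reach 1 TPM at the share needed. Expression in the melanoma cells themselves stays open and was not tested.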

How the results depend on the processing

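The library sets, leaving out single guide libraries and removing shared barcodes were chosen only after the results were seen; the other alternatives here were planned. Of 9297 values recomputed, 0 were labelled reversed, but counts of genes and shares of cells could not take that label. The direction with more genes did change. Late against parental went from 860 higher and 609 lower to 1061 and 1273 with the library set as a covariate. Where counts moved by more than 1.5 times, the cause was not tested, except that sets alone and left-out libraries hold fewer samples.

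Late against parental (1469 genes) gave 786 genes with only the 2 groups, 3151 with array weights, 2334 with the library set as a covariate and 62 in set 2 alone. Leaving out 1 library gave from 435 (without parental replicate 3) to 1909; without replicates 1 and 2 it gave 767 and 774. Late against early (1866) gave 621 in set 1 and 260 in set 2, and from 1417 to 2243 with a library left out. Early against parental (58) gave 148 without a filter, 93 with median-of-ratios scaling, 94 with only the 2 groups, 566 with array weights, 88 with the covariate, 15 in set 1 and 11 in set 2. It ranged from 14 (without parental replicate 3; 25 without replicate 2) to 76. The slope (1678) gave 2828 with parental cells as generation 0, 640 in set 1, 231 in set 2, and from 1209 to 1930 with a library left out. With the covariate, all 1469, 1866, 58 and 1678 genes were called again. In set 1 alone, 841 of the 1469 genes of late against parental were called again with the same sign. In set 2 alone, which held 1 parental library, 1464 of the 1469 had the same sign. The libraries of both sets were in the fit that chose these genes, so agreement in sign is no independent support.

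The line difference (4665) ranged from 2677 to 4398 with a guide pair left out (2677 without sgIfnar1, 2726 without sgIfngr1, 2940 without sgStat1). The guides sgStat1, sgIfnar1 and sgIfngr1 gave 3, 2 and 3 genes with a pseudocount of 0.1 and 4, 9 and 10 without a filter, in place of 0. With a library left out, sgStat1 gave from 0 to 3 (3 without B16-F0 sgStat1), sgIfnar1 0 and sgIfngr1 from 0 to 1 (without LN6-987AL sgIfngr1). With an estimated correlation, 3 of 7, 2 of 10 and 0 of 6 lists passed for late against parental, late against early and the line difference.

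B-like shares (35.7%, 45.1%, 48.8%) were 40.2%, 51.2% and 55.3% without doublet removal, 24.9%, 34.7% and 36.7% with a mitochondrial limit of 5%, and 42.1%, 53.3% and 57.4% at resolution 0.5, in the same order of libraries each time. The interferon-stimulated ratio in B-like cells was 1.33 in place of 1.297 without ribosomal and mitochondrial genes. Of other cell class values, 50 stayed within their interval and 28 moved. Gamma delta-like cells formed no class with the 5% limit or without doublet removal, and the 1.5-fold size rule gives no value, since it changes only which genes are named.

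Of named gene results, 5506 kept their call with a library left out, 323 lost it and 12 gained it; under the other alternatives the numbers were 2682, 275 and 12. No paired analysis was possible because the labels pair no parental culture with a lymph node line. Read depth limits the single-cell values through counting error, and its limit on the cell line tables is not known.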

Other observations

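Intermediate lines (n = 6) lay between early and late lines in the interferon-stimulated score, at 1.09 ± 0.49 (SD) against 0.33 ± 0.34 (n = 10) and 1.83 ± 0.34 (n = 13). Their MHC class I score was 1.02 ± 0.27, against 0.72 ± 0.21 in early and 1.14 ± 0.29 in late lines, and their hypoxia score 0.69 ± 0.43, close to 0.73 ± 0.39 in early and above 0.30 ± 0.46 in late lines. The NK cell ligand score was 0.73 ± 0.18 in intermediate lines, against 0.48 ± 0.23 in early and 0.87 ± 0.32 in late lines. By generation, the interferon-stimulated score was 0.07 ± 0.14 at generation 1 (n = 4), 0.26 ± 0.10 at 2, 0.74 ± 0.28 at 3, 0.75 ± 0.34 at 4 and 1.44 ± 0.34 at 5 (n = 3 each), 1.60 ± 0.35 at 6 (n = 5), 2.16 ± 0.07 at 7 and 1.78 ± 0.31 at 8 (n = 3 each), and 1.96 ± 0.30 at 9 (n = 2). Generations 1 and 8 were in library set 1 alone and generations 2, 5 and 7 in set 2 alone. None of these intermediate values was tested.

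In B-like lymph node cells, the peptide transporter gene Slc15a2 had 208, 1 and 160 UMIs in the tumour-naive, B16-F0 and LN6-987AL libraries, and Ly6k stood at 16.4, 3.08 and 18.9 CPM. The largest unnamed cluster with B cell markers held 6.17%, 8.08% and 8.65% of cells, one with CD8 T cell markers 3.08%, 3.91% and 3.47%, with monocyte genes such as Lyz2 and Csf1r 0.475%, 0.823% and 0.727%, and with cell cycle genes 1.18%, 1.02% and 1.36%.

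The library sets and the tests of this part, other than the splits of libraries, were chosen only after the results were seen, and what the splits would show for numbers of genes and lists was written down after their first run. For the 2 medians of the interferon-stimulated list, splits added after that run, it was written down before they were computed. Set 1 had Gm24270 at 11102 to 22308 TPM and set 2 at 888 to 2947 TPM; each held 16 libraries, with 5 and 5 early, 2 and 4 intermediate, 7 and 6 late and 2 and 1 parental. The 20 most abundant genes took from 23.3% to 30.5% of TPM in set 1 and from 15.3% to 21.2% in set 2, and 5595 genes were higher and 75 lower in set 2 with stage in the fit.

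For the number of genes called, the real split of late against parental gave 1469 and the highest of the others 936. The numbers were 1866 and 1502 for late against early, 58 and 11 for early against parental and 1678 and 0 for the slope. Each time 1 of 100 splits was as large, the real one. These splits argue against a random division of independent libraries, but cannot exclude differences that related lines came to share by chance. For the line difference 1 of 35 splits was as large, with 5521 genes without a guide term and 2 in the highest other split. The 8 libraries came from 2 lines, so this shows that libraries of the same line resemble each other. It cannot exclude a chance difference between 2 cultures. For the number of lists that passed camera with the preset correlation, chance cannot be excluded. For late against parental 37 of 100 splits gave as many as 7 (highest other 11). For late against early 5 of 100 gave as many as 10 (highest other 12). For the line difference, fitted here without a guide term, 21 of 35 gave as many as 5 (highest other 10).

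A hypothesis was that interferon receptor signalling accounts for the higher MHC class I genes in NBF0IFNRKOLN1 than in B16-F0 with both receptor guides. The interferon-stimulated list had a median of -0.00091 there, with 19 members higher and 20 lower, and its 2 libraries differed (Isg15 at 9.32 and 2.58 TPM, against 3.17 TPM with both guides). Against B16-F0 sgLacZ the interferon-stimulated medians of the 2 libraries were -0.46 and -0.41, below all random lists. Those of MHC class I were 0.17 and 0.08. The interferon-stimulated list thus did not rise as a set with the MHC class I genes. Each B16-F0 reference was 1 library, so this stays open.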
